A study of Mus musculus with 4 samples.

How the data were processed

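CTCF, a zinc-finger protein that binds a long DNA motif and anchors many chromosome loops, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in gastrocnemius, the large calf muscle. The tissue came from adult female mice of the B6CASTF1/J hybrid strain at 2 months of age. The 4 libraries fall into 2 groups, pool E and pool F, each a pool of 2 tissue samples and each with 2 technical replicates. Per the labels' protocols the tissue was frozen before chromatin was prepared, and fragments of 200 to 600 bp were kept. The hybrid genome was analysed against mm10 (GRCm38), so no allele was told from the other.

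Per the notes deposited with each sample, the technical replicates of a pool were merged into 1 alignment, and a single control alignment served both pools. The aligner, the peak caller and their versions were not given in the sources used here. There were 4 ranked peak lists and 4 thresholded lists made from them by the irreproducible discovery rate (IDR), which compares the order of peaks in a pair of inputs. The pool E list and the pool F list rest on 1 pool each, and the conservative list and the combined list rest on both. In the list headed conservative, the strengths of the first input matched the ranked pool E list for 76.2% of the ranked peaks and those of the second matched the ranked pool F list for 60.5%; no first input matched pool F and no second input matched pool E. The thresholded lists also draw on a further file that was not described, and they hold chromosomes 1 to 19 and X.

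The peak strength is a score that the authors deposited with each peak; its scale was not stated, so it served to rank and describe peaks within a list. The exception is the ratio of strengths between the 2 inputs of a ranked list, given as a description without a test. The ranked lists hold the −log10 of the IDR as the authors deposited it, and peaks at an IDR of 0.05 or less make up the thresholded lists apart from peaks on other sequences and a few others. Read depth was unknown, since none of the lists gives read counts. Shares of peaks or genes have 95% Wilson intervals, which cover counting error only: they take peaks as independent and leave out differences between animals. The technical replicates are merged in every list, so no value has a spread between replicates.

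The conservative list was the main list, chosen before the data were examined, as were the tests, windows, gene lists, loci and the alternatives called planned. Peak pairs counted as shared at a reciprocal overlap of 50%, found with bedtools 2.31.1, against 100 shuffles of positions within chromosomes. Summits were placed in promoters (within 1000 bp of a gene start), exons, introns or intergenic sequence by GENCODE M21 with 53843 genes, against 100 shuffles within chromosomes outside assembly gaps. The smallest two-sided p that 100 shuffles can give is 0.020, and the smallest one-sided p is 0.0099. Peaks per Mb used chromosome length outside gaps, and relations across the 19 autosomes were tested with 100000 permutations.

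The motif was the consensus CCASYAGRKGGCRS, in which S stands for C or G, Y for C or T, R for A or G and K for G or T. A match had at most 2 mismatches and a centre within 50 bp of the summit, and windows displaced by 2000 bp to each side gave the background. Orientation was taken from neighbouring summits with a motif within 200 kb: convergent pairs have the left motif on the plus strand and the right motif on the minus strand, divergent pairs the reverse, and tandem pairs share a strand. Strands were shuffled within chromosomes 10000 times.

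For each of 18 gene lists, the share of genes with a summit within 5000 bp of the gene start was set against 10000 random lists matched in gene length and local gene density, each in 5 classes, with a two-sided permutation p and Benjamini-Hochberg adjustment over the lists. For each of 16 loci, summits per 100 kb were taken from 50 kb before the first gene to 50 kb after the last. They were set against 1000 windows of the same length at random positions outside gaps on the 19 autosomes. These windows were not matched in gene density, and loci on the X were set against them too. Genes of a cluster share peaks and lie in one chromatin neighbourhood, so they are not independent, and p-values for clustered lists are too small by an unknown amount.

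Symbols Tf, Znf143, Cnbp2, Atp5f1a, Atp5f1b, Atp5f1c and Bmal1 were read as Trf, Zfp143, Zcchc13, Atp5a1, Atp5b, Atp5c1 and Arntl. From the X-linked list, Linx and Xpa were left out because the annotation has no X-linked gene of that symbol. Genes were named by a rule: the 10 genes with the strongest summit within 1000 bp of their start; the 3 members of each list with the strongest summit within 5000 bp and the first member listed without one; each locus with its count and strongest peak; and the 5 strongest peaks. The text gives all of these for the called lists and, for the other lists, the member with the strongest summit and the first without one. The result of 1 gene that the rule takes is not reported here. Any further gene, and the motif content of the lists and loci, was chosen after values were seen. So was every division of peaks by strength class, distance class, repeat content or gene family, with these exceptions. The 21082 strongest peaks and the stronger part of the ranked peaks were set before the data were examined. For tests by strength class or repeat content among the results flagged for a closer look, the order is given there.

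Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The promoter, motif, orientation, gene list and locus tests were first tested on simulated data; the overlap, correlation, sign and Fisher tests were not. With 42163 uniform peaks the promoter share was 1.02 times the shuffled one. All planted motifs among 995 were found on the planted strand. Random strands for 32727 motifs gave a convergent share of 25.2%. Among 53843 genes, 3 percent of random lists of 40 passed p of 0.05. Of 50 lists of 40, 100% did once 50% of their genes had been given a summit. That is a large effect, and smaller ones were not simulated. Random windows over 42163 uniform peaks passed in 1 percent.

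The alternatives were each of the other lists, the 21082 strongest peaks, an IDR of 0.01, other overlaps, promoter windows, gene starts, mismatches, motif windows, a learned weight matrix, neighbour distances, list windows, unmatched random lists and other flanks. Added after the data were seen were protein-coding genes only, summits with a motif only, and windows on the X for X-linked loci. So were neighbours 50 kb to 500 kb apart, 3 mismatches, and all peaks per Mb of unmasked length. Allele-specific binding, read coverage and the control alignment were not analysed here.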

Results

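CTCF binding in calf muscle was described by the peaks that the depositors called in 2 pools of gastrocnemius from female hybrid mice, each pool merging 2 technical replicates. The conservative list held 42163 peaks with a median width of 294 bp and a median strength of 245.6 (quartiles 116.5 and 432.1; strength is the authors' score). The combined list held 49649 peaks, the pool E list 50899 and the pool F list 33784. The strongest peak of the conservative list lay between genes at 60834973 to 60835317 on chromosome 10 (mm10), 3573 bp from the start of Unc5b, a netrin receptor gene, with a strength of 684. The next 4 lay in an intron of Akna at 63368599 to 63368939 on chromosome 4 (672.5), at the start of Hoxa7 at 52221646 to 52221997 on chromosome 6 (671.6), and between genes at 45030795 to 45031221 on chromosome 13 (669) and 47038878 to 47039215 on chromosome 17 (668.5). Depth was unknown, and without separate lists per replicate no error between replicates can be attached to these numbers.

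The first comparison asked how far the peaks of the 2 pools coincide. Of the pool E peaks, 26552 (52.2%, interval 51.7 to 52.6) had a partner in the pool F list, and of the pool F peaks 26514 (78.5%, interval 78.04 to 78.9) had one in the pool E list. Shuffled positions gave 0.276% and 0.412% (one-sided permutation p = 0.0099 for each, the smallest that 100 shuffles can give). The conservative list had partners for 87.8% of its peaks in the pool E list, for 66.2% in the pool F list and for 97.4% in the combined list, which draw on the same reads. Pool E peaks with a pool F partner had a median strength of 217.1, and those without one 52.2. The share rested on the overlap required: with 1 bp it was 63.7% of pool E and 95.4% of pool F peaks, and with a reciprocal overlap of 80% it was 9.32% and 14.03%.

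Peak strength gave a similar order to sites found in both pools. Every ranked peak has a strength in both inputs, so peaks of 1 input alone are not covered. Across the 102748 ranked peaks behind the conservative list, Spearman's rho between the 2 inputs was 0.885 and Pearson's r on the log2 scale 0.930; peaks are not replicates, and these values describe the pair of inputs. The IDR threshold was met by 41.0% of ranked peaks; rho among these was 0.975, a value raised by a threshold that selects peaks ranked alike. There the strengths of the first input, matched to pool E, exceeded those of the second, matched to pool F, by a median log2 ratio of 1.03 (SD over peaks 0.39). In the lists made within a pool, the SD of that ratio was 0.34 in pool E and 0.34 in pool F around medians of 0.00. No test applies, since the strength scale of each input was not stated.

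CTCF peaks gathered at gene starts and were sparse between genes. Promoters held 5946 summits, or 14.1% (interval 13.8 to 14.4), against 3.97% of shuffled summits (SD 0.0948), a 3.55-fold difference. Exons held 6.78% against 4.10%, introns 44.3% against 41.9%, and intergenic sequence 34.9% against 50.01%. Each differed from the shuffles (two-sided permutation p = 0.020, the smallest they can give). The shuffles were not matched in repeats: 33.7% of shuffled summits lay in masked repeats, against 19.7% of summits. How much of each difference comes from this was not tested. The intron excess did not remain among the 21082 strongest peaks, at 42.2% (permutation p = 0.634).

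The strongest peak at a gene start lay 27 bp into Hoxa7, a homeobox gene of body axis patterning, with a strength of 671.6, rank 3 of all peaks. It was followed by peaks at the long noncoding gene 4833412C05Rik on chromosome 7 (666.1) and at Gins4 on chromosome 8 (663.8), which encodes a subunit of a DNA replication complex. A single peak on chromosome 17 (660.6) lay at the starts of AI413582 and of C130040N14Rik. Peaks at Srp9 (656), a signal recognition particle gene, and Erlin2 (655.9), an endoplasmic reticulum gene, came next. Tfeb (655.7), a regulator of lysosome genes, Pafah2 (652.5), which encodes an acetylhydrolase of platelet-activating factor, and Ephb1 (651.8), an ephrin receptor gene, completed the 10. All of these summits except that at Erlin2, 401 bp into the gene, had a motif with at most 2 mismatches.

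The X chromosome carried fewer CTCF peaks per Mb than any autosome. It held 1163 peaks, or 7.11 per Mb, while the 19 autosomes ranged from 12.9 on chromosome 3 to 26.5 on chromosome 11 with a median of 17.2. The X is 1 chromosome, so no test against the autosomes was made; the tissue was female, with 2 X chromosomes in each cell. Masked repeats made up 46.8% of the X and 30.6% to 35.8% of the autosomes. With all peaks counted, those in masked sequence included, the X had 13.4 per Mb of unmasked length against 20.1 on the lowest autosome. The median strength of X peaks was 214.2, and the autosome medians ran from 221.7 to 265.1.

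Among autosomes, peak density rose with gene density. For protein-coding genes per Mb, Pearson's r was 0.868 and Spearman's rho 0.874 over 19 autosomes (permutation p = 1e-05, the smallest possible, and 2e-05; adjusted over 4 relations 2e-05 and 4e-05, two-sided). Without chromosomes 7 and 11, r was 0.889. For all annotated genes, r was 0.600 and rho 0.646 (permutation p = 0.0093 and 0.0035; adjusted 0.0093 and 0.0047), and r was 0.731 without chromosomes 7 and 18. For exact matches to the motif consensus per Mb, r was 0.897 and rho 0.872 (permutation p = 1e-05 for both; adjusted 2e-05 and 4e-05), and r was 0.894 without chromosomes 11 and 5. The relation with the masked share had r = -0.623 and rho = -0.514 (permutation p = 0.0047 and 0.026; adjusted 0.0063 and 0.026); without chromosomes 11 and 3 it fell to r = -0.378 and rests on them.

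**Figure D1:**
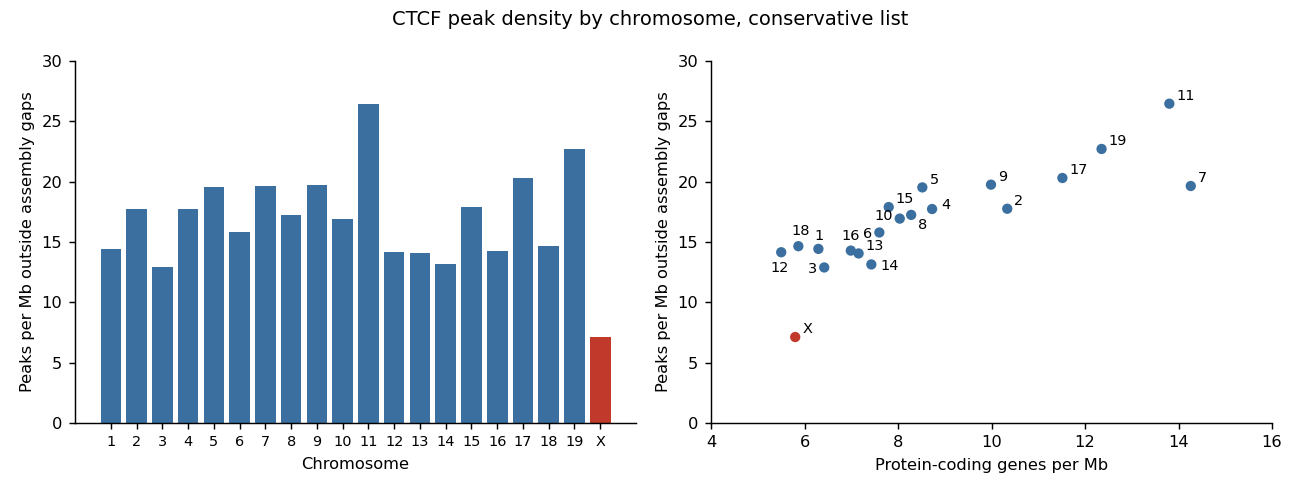
Peaks of the conservative list per Mb outside assembly gaps for each chromosome (left, bars) and against protein-coding genes per Mb (right, 1 point per chromosome, labelled), with the X in red. The X stands at 7.11 per Mb, below all 19 autosomes, which run from 12.9 to 26.5.

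Most summits lay on the CTCF motif. Of the 42163 summits, 32727 (77.6%, interval 77.2 to 78.02) had a match within 50 bp, against 3.17% of displaced windows. The best match had no mismatch at 5147 summits, 1 at 13891 and 2 at 13689, so the share depends on the mismatches allowed. The motif was more frequent at the summit than in the displaced windows for 32691 peaks and less frequent for 570, and the exact two-sided sign test gave a p too small for the software to represent. The median distance between motif centre and summit was 6.5 bp, and 67.5% of the motifs lay within 10 bp. The share rose from 60.9% in the weakest of 10 strength classes (interval 59.4 to 62.4) to 91.3% in the strongest (interval 90.4 to 92.1). It was 73.4% in the pool E list and 80.7% in the pool F list. A weight matrix learned on odd-numbered autosomes found a match at 84.6% of summits on even-numbered ones and in 4.80% of displaced windows.

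Motif content followed location. Intergenic summits had a motif in 82.9% of cases (interval 82.3 to 83.5), intronic ones in 80.7%, exonic ones in 74.6% and promoter summits in 56.3% (interval 55.0 to 57.5). Promoters held 27.5% of the summits without a motif and 10.2% of those with one. In the genome, 5160 of 6562 exact matches to the consensus carried a summit (78.6%, interval 77.6 to 79.6). Sites with 1 mismatch carried one in 24.4% of 57894 cases, and sites with 2 mismatches in 3.30% of 484486.

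**Figure D2:**
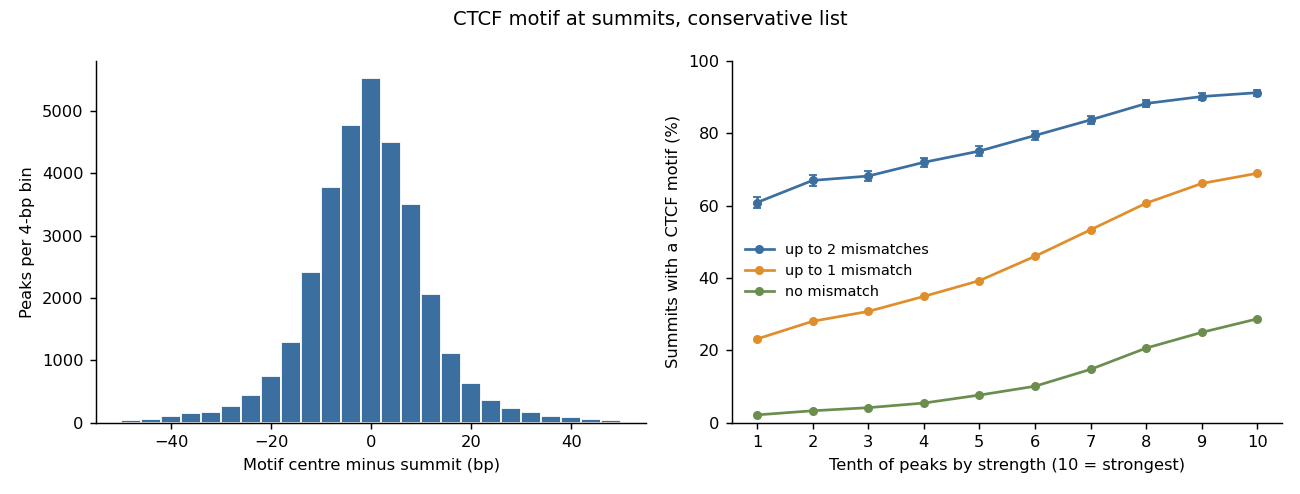
Distance from summit to motif centre in bp (left, number of peaks in bins of 4 bp) and share of summits with a motif by class of peak strength (right, in percent, class 10 strongest; bars are 95% Wilson intervals on the upper line). The share with at most 2 mismatches rises from 60.9% to 91.3%.

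CTCF motifs at neighbouring peaks pointed toward each other less often than shuffled strands did at short range and more often at long range. Over 30229 neighbouring pairs within 200 kb, 23.5% were convergent (interval 23.0 to 24.0) against 25% with shuffled strands, and 51.3% were tandem against 50% (two-sided permutation p = 0.00020 for each, the smallest possible). Divergent pairs made up 25.2% against 25% (permutation p = 0.296), a result that turned with the setting: 24.6% in the pool E list (p = 0.0024), 25.9% in pool F and 27.8% among the 21082 strongest peaks (p = 0.00020 for both). The convergent share rose with distance, from 17.3% (interval 15.7 to 19.03) of pairs within 2000 bp to 22.1% at 10 to 50 kb, 29.1% at 50 to 100 kb, 33.4% at 100 to 200 kb and 37.1% (interval 34.9 to 39.4) at 200 to 500 kb. Divergent pairs made up 24.6% within 2000 bp and went from 27.9% at 2000 to 10000 bp to 17.4% at 200 to 500 kb. The direction of the convergent result thus turned with the distance: for pairs 50 to 500 kb apart the share was 31.8% (permutation p = 0.00020), an alternative chosen after the data were seen. Among the 21082 strongest peaks and with 1 mismatch, the tandem share was 48.4% and 49.4%; the first lay below the shuffled one (permutation p = 0.00020) and the second did not pass (permutation p = 0.144).

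**Figure D3:**
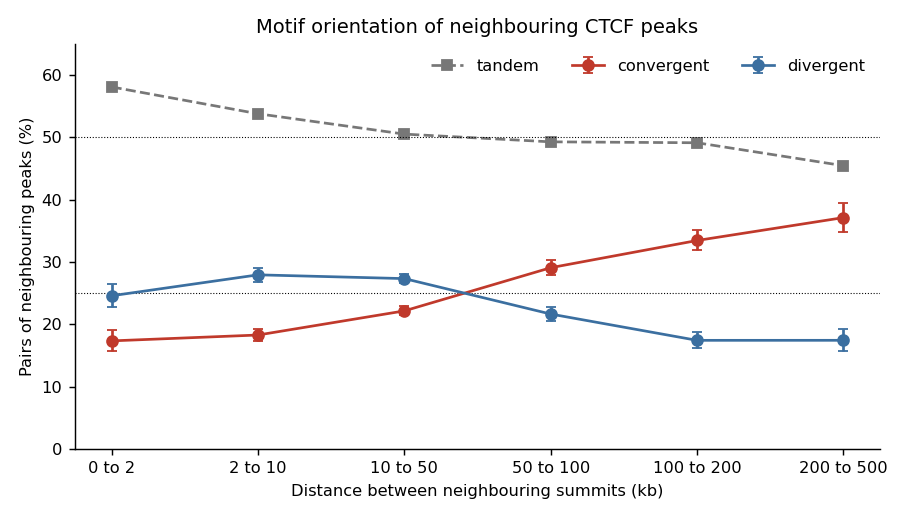
Share of convergent, divergent and tandem motif pairs (percent of neighbouring pairs) by distance between summits in kb; bars are 95% Wilson intervals, and dotted lines mark the 25% and 50% that random strands give. Convergent pairs rise from 17.3% within 2 kb to 37.1% at 200 to 500 kb.

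Genes of the contractile apparatus and metabolism of skeletal muscle had CTCF near their starts more often than matched genes. A summit lay within 5000 bp of the start of 32 of 51 such genes (62.7%, interval 49.0 to 74.7), while random lists averaged 36.8% (central 95% from 23.5 to 50.98; two-sided permutation p = 0.00080, adjusted p = 0.0036 over 18 lists). The strongest of these peaks lay 780 bp into Ckm, the muscle creatine kinase gene, with a strength of 619 and an exact match to the motif. Peaks of 566.1 and 558.6 lay near Cox6a2, a muscle subunit of cytochrome c oxidase, and Ankrd2, a stretch-responsive muscle gene. The summit nearest to Mb, the myoglobin gene, lay 18130 bp away. Motifs were present at 43 of the 48 summits (89.6%), against 69.2% of other summits near gene starts (exact Fisher test, two-sided, p = 0.0015, adjusted p = 0.0087). The Fisher tests, here and for the other lists, were not matched on location. Among all summits, those at promoters had a motif in 56.3% of cases, intronic ones in 80.7% and intergenic ones in 82.9%. How much of the difference comes from location was not tested. Within 1000 bp of the start, 17.6% of the genes had a summit, slightly below the random lists (adjusted permutation p = 0.911), and within 20000 bp, 78.4% did (adjusted permutation p = 0.132).

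The clustered protocadherin genes, which encode cell adhesion proteins of neurons, had a summit at 42 of 57 starts (73.7%, interval 61.0 to 83.4) against 42.8% of random lists (permutation p = 0.00020, the smallest possible; adjusted p = 0.0012). The strongest lay at Pcdhgc3 (376.3) and at Pcdhgb8, whose peak (347.4) was also the strongest within the window of Pcdhga12; the summit nearest to Pcdha1 lay 23035 bp away. By cluster, chosen after values were seen, a summit lay within 1000 bp of 19 of 22 beta starts, 19 of 22 gamma starts and 3 of 14 alpha starts. Among the beta and gamma starts with a summit, the median distance was 65 and 64 bp. Only 7 of the 41 summits near the listed genes had a motif (17.1%; exact Fisher test, adjusted p = 1.2e-10). The list's excess ended among the 21082 strongest peaks, at 19.3%, and turned with motif-bearing summits only, at 14.04%.

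Imprinted genes, expressed from 1 parental copy, had a summit at 31 of 57 starts (54.4%, interval 41.6 to 66.6) against 34.0% of random lists (permutation p = 0.0016, adjusted p = 0.0058). The strongest lay at H13 (611.5), which encodes a signal peptide peptidase, and near Cdkn1c (574.6), a cell cycle inhibitor gene, and Slc22a18 (553.3), a transporter gene; Igf2, a growth factor gene, had its nearest summit at 5524 bp. With protein-coding genes only, the share was 53.1% and the adjusted permutation p = 0.106. It was 29.8% within 1000 bp (adjusted permutation p = 0.129) and 35.1% with motif-bearing summits only (adjusted permutation p = 0.140).

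Olfactory receptor and keratin genes had few CTCF peaks near their starts. Of 1106 olfactory receptor genes, 32 had a summit (2.89%, interval 2.06 to 4.06) against 34.1% of random lists, and of 50 keratin genes 3 did, 6% against 37.0% (permutation p = 0.00020 and adjusted p = 0.0012 for each). The olfactory receptor genes with the strongest peaks were Olfr94 (649.2), Olfr649 (575.5) and Olfr71 (546.1), and the summit nearest to Olfr1416 lay 31152 bp away. The keratin genes with a peak were Krt28 (593.7), Krt222 (124.9) and Krt36 (71.6), and the summit nearest to Krt24 lay 7767 bp away. Within 20000 bp, 58% of the keratin genes had a summit and the call ended (adjusted permutation p = 0.132).

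With the conservative list no other gene list passed the test (two-sided permutation, adjusted over 18 lists); a gene without a peak had none within 5000 bp of its start. Hox genes had a summit at 59.0% of 39 starts (adjusted permutation p = 0.061), with Hoxa7 strongest and none within 5000 bp of the start of Hoxd11, and passed among the 21082 strongest peaks (48.7%, adjusted permutation p = 0.0045) and with pool F (0.036). Oxidative phosphorylation and citrate cycle genes stood at 54.1% of 37 (adjusted permutation p = 0.061), with no summit near Ndufa1; it passed with the combined, pool E and pool F lists (adjusted permutation p = 0.021, 0.022 and 0.0084). Core circadian clock genes stood at 56.5% of 23 (adjusted permutation p = 0.130), Bhlhe40 strongest (627.8) and Clock without a peak; they too passed with those lists (adjusted permutation p = 0.025, 0.0086 and 0.033). Only 5 of their 22 summits had a motif (22.7%; exact Fisher test, adjusted p = 8.1e-05). Muscle transcription factors and satellite cell genes stood at 48.6% of 35 (adjusted permutation p = 0.117), Sox6 strongest (556.6), and passed within 20000 bp (82.9%, adjusted permutation p = 0.0072) and without matching (adjusted permutation p = 0.013), while Myf5, a muscle lineage regulator, had its nearest summit at 12389 bp. Cohesin, CTCF and chromosome architecture genes stood at 54.1% of 37 (adjusted permutation p = 0.146): Esco1, a cohesin acetyltransferase gene, was strongest (584.3), Ctcf itself followed (547.1), and Ctcfl had none.

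Leaving aside the olfactory receptor, keratin and protocadherin genes above, markers of other cells of the tissue and genes of other tissues did not detectably differ from random lists. This holds for the conservative list and 5000 bp. Under other settings some were: histone genes with the combined list (49.3%), pool E (46.5%) and 20000 bp (77.5%; adjusted permutation p = 0.0014, 0.011 and 0.0018), and fibroblast markers without matching (adjusted permutation p = 0.016). With gene bodies, endothelial markers (84.6%) and housekeeping genes (76.7%) passed above the random lists (adjusted permutation p = 0.047 for both). Fibroblast, adipogenic progenitor and tendon markers stood at 52.0% of 25 (adjusted permutation p = 0.166), with Col1a1, a collagen gene, strongest (577.1) and none near Dcn. Endothelial and mural cell markers stood at 26.9% of 26 (adjusted permutation p = 0.520), with Myh11, a smooth muscle myosin gene, strongest (476.1) and none near Pecam1. Immune cell markers stood at 24.1% of 29 (adjusted permutation p = 0.367), Cx3cr1 strongest (630.5) and Ptprc without one. Neuronal and Schwann cell markers stood at 40.0% of 25 (adjusted permutation p = 0.637), Neurog2 strongest (606.5) and Snap25 without one. Liver genes stood at 24.0% of 25 (adjusted permutation p = 0.520), Apob strongest (524.1) and Alb without one. Housekeeping genes stood at 43.3% of 30 (adjusted permutation p = 0.520), Actb strongest (618.3) and Hprt without one. Clustered histone genes stood at 32.4% of 71 (adjusted permutation p = 0.302), Hist1h2bl strongest (572.7) and Hist2h3c2 without one. X-linked loci tied to X inactivation and chromosome folding stood at 21.1% of 19 (adjusted permutation p = 0.302), with Eif2s3x strongest (515.9), Xist next (511.2) and none near the start of Tsix.

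**Figure D4:**
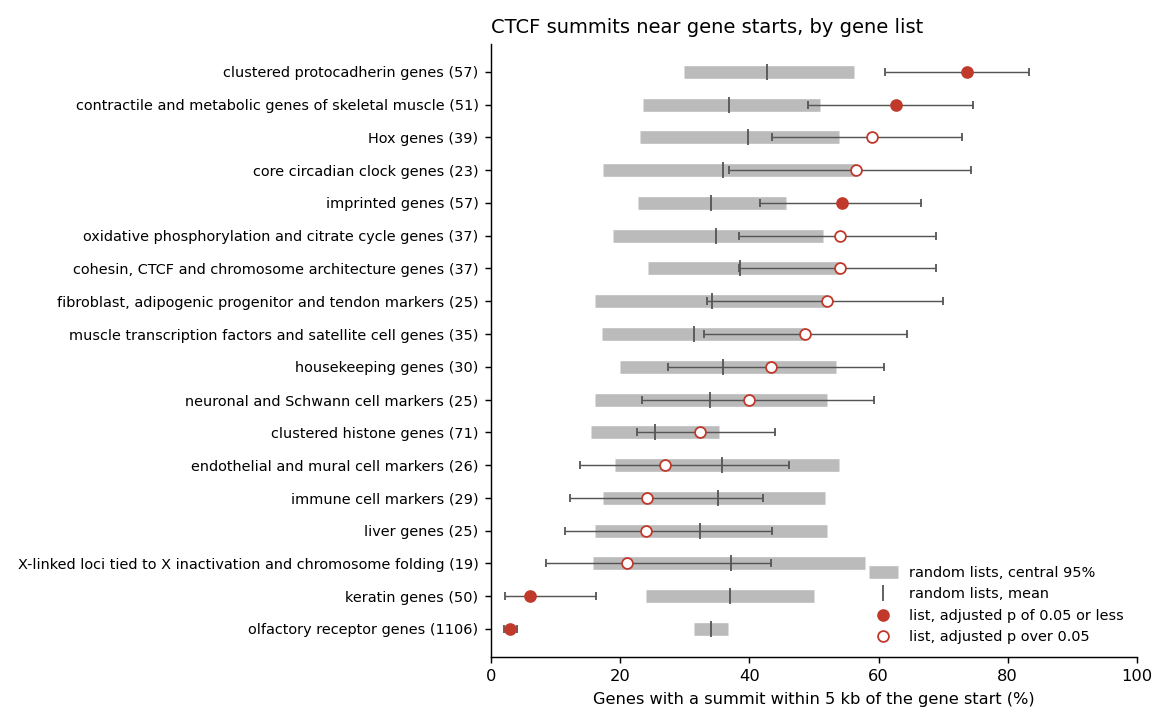
Share of the genes of each list with a summit within 5 kb of the gene start (points, percent; thin lines are 95% Wilson intervals; number of genes in brackets), against matched random lists (grey bars, central 95%; ticks, mean). Filled points mark adjusted p of 0.05 or less: protocadherins at 73.7%, muscle genes at 62.7%, imprinted genes at 54.4%, keratins at 6% and olfactory receptors at 2.89%.

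Of the 16 loci, Firre and the protocadherin gamma cluster were denser in CTCF than random windows. The window around Firre, an X-linked long noncoding RNA gene, held 32 summits at 50505744 to 50685321, or 17.8 per 100 kb, against a mean of 1.57. The window of the protocadherin gamma cluster on chromosome 18 held 26 at 37611793 to 37891873, or 9.28 per 100 kb, against 1.68. Both had a two-sided permutation p of 0.0020, the smallest that 1000 windows can give, and an adjusted p of 0.016. The windows lay on autosomes and were not matched in gene density, while 20 of the 26 gamma summits lay at promoters. The share of the excess that comes from the number of gene starts was not tested. The strongest peak at Firre (572.9) lay 22706 bp before its start, and that of the gamma cluster (610.3) in an intron of Diaph1, the neighbouring gene. Motifs with at most 2 mismatches were found at 6 of the 32 and 4 of the 26 summits. The calls ended with a flank of 200 kb, at 7.09 and 7.07 per 100 kb, and with motif-bearing summits only, at 3.34 and 1.43; that of the gamma cluster also ended among the 21082 strongest peaks, at 3.93.

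**Figure D5:**
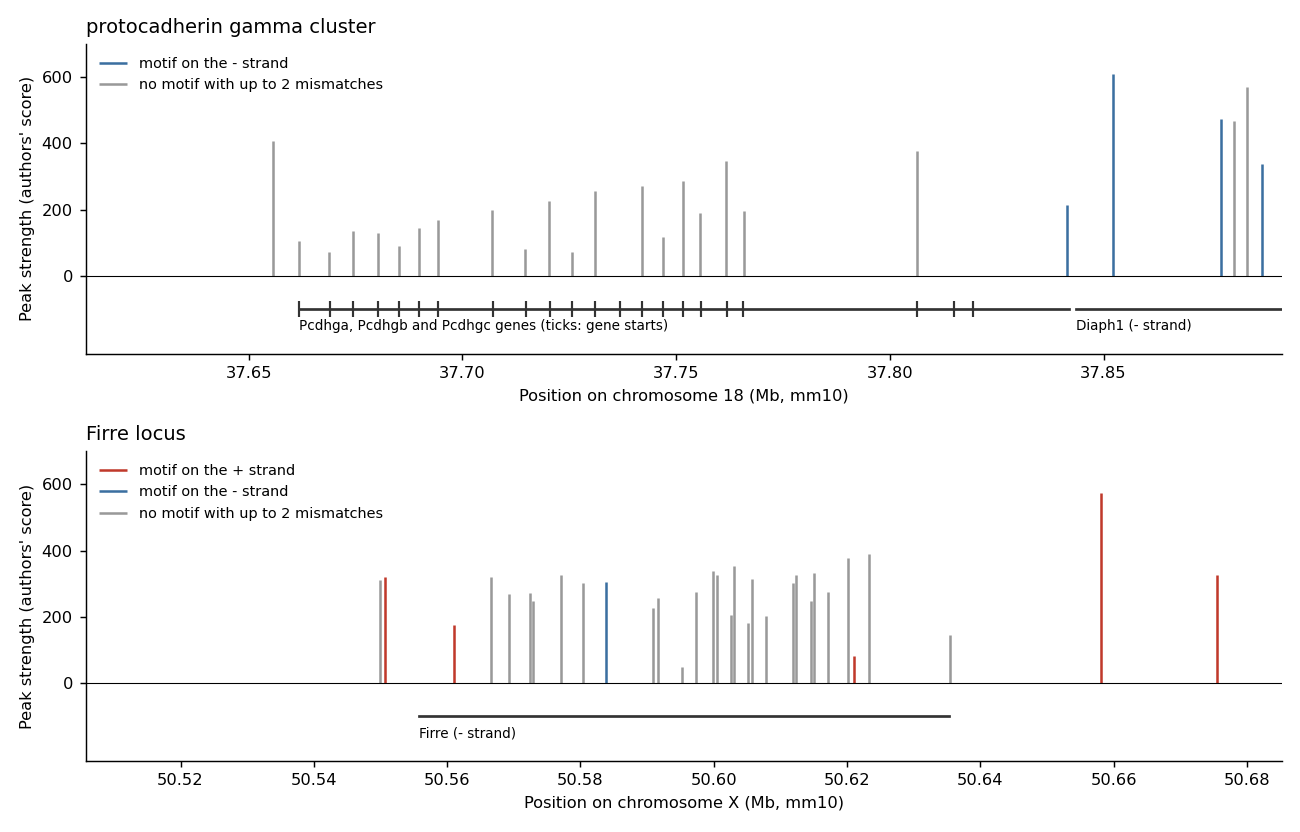
Summits of the conservative list at the protocadherin gamma cluster (top, chromosome 18) and at Firre (bottom, chromosome X), by position in Mb (mm10), with line height giving the authors' peak strength and colour the motif strand. In the upper window 19 of 22 protocadherin gene starts have a summit within 1000 bp, and most of the 32 summits of the lower window lie within Firre.

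The other 14 loci did not pass (two-sided permutation, adjusted over 16 loci). The H19 and Igf2 locus, where CTCF binding upstream of H19 is known to insulate Igf2 on 1 parental copy, held 14 summits or 7.32 per 100 kb (permutation p = 0.050, adjusted 0.160). Of these, 4 lay 2159 to 3886 bp upstream of H19, and its strongest (575) lay at the start of Mrpl23. The protocadherin beta cluster held 22 summits, 6.12 per 100 kb (permutation p = 0.046, adjusted 0.160), and the alpha globin cluster 10, 8.03 per 100 kb (permutation p = 0.030, adjusted 0.160). The beta and alpha protocadherin windows shared their strongest peak (356.5), and the alpha window held 5 summits.

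The Hox clusters held 10 (HoxA), 13 (HoxB), 5 (HoxC) and 10 (HoxD) summits, strongest at Hoxa7 (671.6), near Hoxb8 (559.8), at Hoxc10 (532.1) and between genes of HoxD (558.6). The cluster of fast and embryonic myosin heavy chain genes on chromosome 11 held 16, with the strongest (546.5) in an intron of Myh13 and 14 with a motif, 11 of them on the minus strand. The Kcnq1 and Cdkn1c locus held 18 (strongest 579.3, 5465 bp from the start of Cdkn1c), the Dlk1 and Meg3 locus 5 (556.2) and the X inactivation centre 20, with the strongest (511.2) 984 bp before Xist. The beta globin cluster held 1 summit (151.7), and the Myf5 and Myf6 locus 3 (433.8). Adjusted permutation p-values of these loci and of the protocadherin alpha cluster ran from 0.356 to 1.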

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

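In this part some tests were chosen only after the results were seen. They were the tests of sites used in pool E only below its 12725 strongest peaks, and those of matrix matches. Those of 3 mismatches by location, the backward consensus, and masked and unmasked motif sites were so chosen too. The others were written down earlier, before their own results. The count of all peaks per Mb of unmasked length was one of these, but joined the alternatives only after the data were seen.

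Signal lay outside the chromosomes of the thresholded lists, on sequences that none of the comparisons used. At the IDR threshold the ranked list behind the pool E list held 8 mitochondrial peaks and that behind the combined list 4, while those behind the pool F and conservative lists held none. Unplaced scaffolds held 13 peaks in the ranked list behind the pool E list, 9 behind pool F, 12 behind the conservative and 13 behind the combined list. The strongest mitochondrial peak of pool E lay at 15913 to 16272 with a strength of 46.9, and no ranked list held a peak on chromosome Y.

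Pool E listed 50899 peaks and pool F 33784. Background as the whole of the pool E peaks without a pool F partner was argued against by their motif share, 62.2 percentage points above displaced windows. A background part among them stays open, with a motif in 65.2% against 80.9% of the pool E peaks with a partner. Sites used in pool E only were argued against among its 12725 strongest peaks, of which 0 lacked an overlap in the ranked pool F list, which allows up to 0.0236%, and among the next 12725, of which 1 did (0.00786%). Among its 25449 weaker peaks such sites cannot be told apart from weak sites missed in pool F: 20.9% lacked an overlap, 4.68% in the stronger part and 37.2% of the weakest 12724, and the 5331 pool E peaks without one had a motif in 59.2% against 2.87% of displaced windows. Weaker enrichment or lower depth in pool F stays open, because the test set for it cannot decide. Of the 25450 strongest pool E peaks, 16.9% had no partner, between the bounds of 5% and 20% set for it. Having a partner depends on peak width as well as on position. The median width was 327 bp in the pool E list and 241 bp in the pool F list. Only 0.754% of these strongest peaks had no overlap at all in the pool F list. Other differences between the animals of the pools were not tested.

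The X had 7.11 peaks per Mb, below every autosome. Exact motif sites were also fewer per Mb on the X, at 1.46 against 1.73 to 3.93 on the autosomes. Fewer motifs alone did not account for the low peak density, since 55.2% of exact motif sites on the X carried a summit (interval 48.9 to 61.4) against 70.0% on the lowest autosome. Repeats in which reads cannot be placed stay open. The X had 13.4 peaks per Mb of unmasked length against 20.1 on the lowest autosome, below the range set for that explanation. But the count takes all peaks, those in masked sequence included, and masking does not show where reads can be placed. On the autosomes most masked exact sites carried a summit. Weaker signal from the inactive X cannot be told apart, because the median strength of X peaks, 214.2 (interval 203.6 to 229.4), reaches past the lowest autosome median of 221.7. At unmasked exact sites the X share was 73.3%, within the autosome range of 69.6% to 88.1%, while at masked sites it was 17.9% (interval 11.004 to 27.9) against 55.1% to 82.4%; a joint role of motif number and repeats was not tested.

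Promoters held 27.5% of summits without a motif and 10.2% of those with one, and weak peaks were argued against as the reason, since the promoter share was higher without a motif in 4 of 4 strength classes of equal size, at 25.8% to 29.6% against at most 11.6%. Degenerate motifs missed at 2 mismatches were argued against as the whole reason, since with up to 3 promoters still held 32.2% of summits without a match and 12.9% of those with one. A part played by them cannot be told apart from other reasons: the planned test took promoter summits alone and put matches with exactly 3 mismatches 51.6 percentage points above displaced windows, but at other summits without a motif the excess was 58.1 points (difference -6.56, interval -8.94 to -4.18). Yet summits with only such a match were 29.7% of all promoter summits and 14.03% of all others. Those shares also reflect the pattern itself, since a motif was less frequent at promoter summits. Among summits without a motif, the consensus with up to 3 mismatches matched 68.0% at promoters and 74.5% elsewhere. The backward consensus matched 26.8% and 15.1% of the same summits. No biological explanation was tested. A weight matrix matched 26.2% of promoter summits without the consensus and 48.6% of others.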

How the results depend on the processing

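The alternatives chosen only after the data were seen included protein-coding genes only, motif-bearing summits only, X windows and neighbours 50 to 500 kb apart. The others were 3 mismatches and all peaks per Mb of unmasked length. No paired analysis was possible because the pools share only technical replicate numbers and each list comes from 1 merged alignment per pool with no test between pools. Leaving out a replicate was not possible either, and the single-pool lists took its place. There were 57 results and 401 alternatives. A case stayed the same if it kept its side of the threshold, lay within the interval or, for counts, within a set fold of the main value. Direction was not compared where neither setting passed. Results that answer a comparison stayed the same in 121 cases, lost the threshold in 11, gained it in 4, moved in 17 and turned in 8. The other results stayed the same in 201 cases. Of their remaining cases, 26 gained the threshold, all of them gene lists. Another 12 moved, all of them correlations or IDR shares of the other peak lists, and 1 turned. Unknown depth limits every count of peaks. Except where the construction of an alternative gives it, the cause was not tested.

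With the 21082 strongest peaks only, the intron share was 42.2% and the X to autosome ratio 0.354. That ratio was 0.413 in the conservative list and 0.520 per Mb of unmasked length, with the X below every autosome in all. With the 21082 strongest peaks only, divergent pairs made up 27.8%, tandem pairs 48.4% and protocadherin starts 19.3%. There 1 locus passed, with the gamma cluster at 3.93 per 100 kb. The correlation of the inputs was 0.964 in the stronger part of the ranked peaks, split at their median strength, and 0.975 at the IDR threshold, which by construction selects peaks ranked alike. At an IDR of 0.01 and 0.1, 39.1% and 43.3% of ranked peaks passed. Convergent pairs 50 to 500 kb apart made up 31.8%. Divergent pairs, past the threshold in each of these, turned to a deficit of 24.6% in the pool E list and 24.6% within 1 Mb, and were in excess at 25.9% in pool F, 27.2% within 50 kb and 26.9% with 1 mismatch, where tandem pairs were 49.4%, not past the threshold.

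The count of lists passing was 5, and became 9 with the combined list, 8 with pool E, 8 with pool F, 3 within 1000 bp, 8 within 20000 bp, 9 with gene bodies and 11 without matching. Calls were gained by oxidative phosphorylation genes (combined, pool E and pool F lists, 20000 bp, gene bodies, no matching, motif-bearing summits), clock genes (those 3 lists, 20000 bp, no matching) and Hox genes (pool F, the 21082 strongest peaks, 20000 bp, gene bodies, no matching). Histone genes gained one with the combined and pool E lists and 20000 bp, architecture genes with the combined list and no matching, muscle transcription factors with 20000 bp and no matching, fibroblast markers with no matching and housekeeping genes with gene bodies. Within 1000 bp muscle genes stood at 17.6% and imprinted genes at 29.8%; within 20000 bp muscle genes stood at 78.4% and keratin genes at 58%. With gene bodies, endothelial and mural markers turned to an excess, 84.6%. Imprinted genes stood at 53.1% with protein-coding genes only. With motif-bearing summits only, imprinted genes stood at 35.1%, protocadherins at 14.04%, Firre at 3.34 and the gamma cluster at 1.43 per 100 kb, and 0 loci passed. With a 200 kb flank 0 loci passed, Firre at 7.09 and the gamma cluster at 7.07 per 100 kb; wider windows take in sequence outside the loci by construction.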

Other observations

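All divisions in this part were chosen after the data were seen. CTCF peaks lay closer together than shuffled ones: the median distance between neighbouring summits was 21399 bp against 40438 bp, and 18.8% of neighbours lay within 5000 bp against 8.31% (two-sided permutation p = 0.020, the smallest that 100 shuffles can give). Windows of 100 kb held 1.60 summits on average. The densest, at 45000001 to 45100000 on chromosome 19, held 18 among Sema4g, Mrpl43, Twnk, Lzts2, Pdzd7, Sfxn3 and Kazald1. A window at 98700001 to 98800000 on chromosome 11 held 17 around Csf3, Med24, Thra, Nr1d1 and Msl1, the genes of a thyroid hormone receptor and a circadian repressor among them. Windows of 17 and 17 summits spanned Firre on the X. A window at 79700001 to 79800000 on chromosome 10 held 16 among Bsg, Hcn2, Polrmt and Palm.

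The longest stretch without a summit ran from 24170187 to 35517902 on the X, 9617106 bp outside gaps, with 47 protein-coding genes and 62.0% masked sequence. On chromosome 7 a stretch from 7299542 to 12478218 had no summit across 54 protein-coding genes, 42 of them vomeronasal receptor genes (Vmn), which serve pheromone detection. Across gene families of at least 30 members by name, 2 of 331 Vmn genes (0.604%) had a summit within 5000 bp of the start, and 1 of 34 secretoglobin genes (Scgb, 2.94%). Highest stood 59.1% of 44 genes whose symbol starts with Rps (interval 44.4 to 72.3), 58.3% of 36 Fbxo genes and 57.4% of 54 Rpl genes. Ppp genes followed at 57.3% of 75, against 37.4% of all protein-coding genes. Grouping by the start of the symbol does not separate ribosomal protein genes from other genes whose symbols start with Rps or Rpl. No test was run on the families.

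Sites at Firre, H19 and the protocadherin beta and gamma clusters had fewer matches with up to 2 mismatches than the 77.6% of all summits. With up to 3 mismatches, 93.9% of all summits had a match, while 90.6% of the 32 summits at Firre had a match against 18.8% with up to 2, and 10.9% of displaced windows matched at 3. At the protocadherin beta cluster the shares were 77.3% and 31.8%, at H19 and Igf2 85.7% and 35.7%, and at the gamma cluster 42.3% and 15.4%; displaced windows matched at 3 in 18.2%, 17.9% and 17.3%. Against windows on the X, Firre kept the smallest permutation p possible, 0.0020, with a random mean of 0.736 per 100 kb. The X inactivation centre had a permutation p of 0.062 against windows on the X and 0.444 against windows on the 19 autosomes (both two-sided).

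Summits lay in masked repeats in 19.7% of cases against 33.7% of shuffled summits (two-sided permutation p = 0.020, the smallest possible). Motif-bearing summits did so in 22.1% and summits without a motif in 11.4%. Exact motif sites in masked sequence of the X carried a summit in 17.9% of cases against 55.1% to 82.4% on the autosomes, and 32.6% of the exact sites on the X were masked, against 8.60% to 14.96% on the autosomes.

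The share of conservative peaks at an IDR of 0.01 was 65.5% in the weakest of 10 strength classes, 100% in the fifth to the seventh and 94.4% in the strongest. The ratio of the first input's strength to the second's was 2.38 in the weakest class, 2.58 in the third and 1.41 in the strongest. The 5 strongest peaks had IDR values of 0.018 to 0.047. Pool E peaks without a pool F partner had a motif in 65.2% of cases, and pool F peaks without a pool E partner in 80%. Both groups include peaks that overlap the other pool by less than a partner requires. Of the 24347 such pool E peaks, 5331 had no overlap in the ranked pool F list either, with a motif in 59.2%. Of the 7270 such pool F peaks, 25 had none in the ranked pool E list, with a motif in 36% (interval 20.2 to 55.5).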
